A study of Mus musculus with 6 samples.

How the data were processed

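Messenger RNA was measured in 6 libraries of 4T1 cells, a mouse mammary carcinoma line of BALB/c origin that is widely used as a model of aggressive breast cancer. Per the labels, the cells had been nucleofected with Cas9 and either control guide RNAs (3 control libraries, replicates 1 to 3) or guides named for FGFR2 (3 libraries labelled FGFR2 KO, replicates 1 to 3), and were then grown in collagen I gels. Per the labels' protocols, cells were suspended at 100000 cells per ml in collagen I (either 1.2 or 2.4 mg per ml), and droplets of 80 µl gelled for 30 min in low attachment plates before medium with 10% serum was added. The labels do not say which of the 2 collagen concentrations a library came from, nor how long the cultures were kept. Gels were broken up with collagenase at 300 U/ml for 10 min, pipetted, and digested for a further 5 min, so transcripts that respond to warm enzymatic dissociation had time to change before the pellets were frozen. Libraries were made with a stranded poly(A) kit (TruSeq Stranded mRNA), per the labels' protocols.

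The deposited values are whole-number read counts per gene, 1 column per library, not normalized. Per the submitters' processing notes, the tools were FastQC 0.11.9, STAR 2.7.9a (the aligner), featureCounts (the read counter, version not given in the sources used here) and R 4.1.1, and the genome builds hg38 and mm10 are both named without a role. The gene symbols are those of mouse, and 98.4% of the 31017 symbols occur in the GENCODE M21 annotation of mm10. Which annotation release was counted, the strand setting, and how reads that align to several places or lie over 2 genes were treated are not given in the sources used here. Values of overlapping or antisense genes, of near-identical paralogs (Lilr4b, Abcb1a, H2-Q4, H2-Q7, Hspa1b and the histones among the genes named) and of genes with processed pseudogenes, such as the glycolytic enzymes, are uncertain to that extent. No symbol was repeated, 0 rows named no gene, and 13486 genes had 0 counts in all libraries. Columns were assigned to libraries by their names, and 0 columns were left unassigned.

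The library totals were 18402522, 20447719 and 15531790 counts for control replicates 1 to 3 and 18635037, 19545981 and 20171309 for KO replicates 1 to 3. The 2 groups were compared with edgeR 4.0.16 in R 4.3.3 on the counts as deposited: low genes were removed with filterByExpr at its defaults (a minimum count of 10 and a total of 15), libraries were scaled with TMM, and a model with the group as its only term was fitted and tested with the quasi-likelihood F-test. The Benjamini-Hochberg adjusted p had to lie below 0.05, with no minimum fold change. Log2 fold changes are KO over control with edgeR's prior count of 0.125, their standard errors (SE) were taken as the fold change divided by the square root of F, and CPM are counts relative to the TMM-scaled library total, as edgeR's cpm gives them, computed here from the deposited counts. Intervals have a confidence level of 95%.

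In all, 35 gene lists were fixed from textbook knowledge before the data were examined, and 737 of their 786 members matched a symbol in the table directly, 26 through a synonym, 20 repeated another member and 3 had no match. Lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1) with its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists tested. Camera with a correlation estimated per list was run beside it. The genes named were chosen by a rule also fixed before the data were examined. It took the FGF receptors and all members of the list of ERK pathway genes. It took the 10 largest rises and the 10 largest falls among genes with an adjusted p below 0.05, a mean of at least 5 CPM and no overlap between groups, without predicted gene models and pseudogenes. It also took, for each list that passed camera or had at least 3 changed members, the 4 members with the smallest adjusted p. Further members that are named as low in adjusted p, as exceptions to their list's direction or as other cell type markers were chosen after their values were seen. Positions are from GENCODE M21 (mm10).

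Counts of replicate pairs were compared by a chi-square test over genes before averaging. The labels number the replicates but do not say that they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical in part. The test was checked on simulated counts for this comparison, with the real means, library sizes and dispersion over 12061 genes and 50 genes seeded at each of 4 fold sizes. It recovered 72% of genes changed 1.25-fold, 84% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, while 5.35% of its calls were genes that had not been changed. Far fewer genes were changed in the simulation than were called in the data (54.6% of tested genes). The adjusted p depends on that share, so these percentages need not hold for the real comparison. A simulated list raised 1.5-fold was called by camera and 0 other lists were. The simulated counts were drawn independently for each gene, so this does not show how often camera calls lists whose members vary together. The alternatives were RLE, upper quartile and total count scaling, DESeq2 1.42.0, limma-voom, no low count filter, a filter of 5 CPM in 3 libraries, a minimum fold change of 1.5 (glmTreat), the replicate number as a block, leaving out each library in turn, and for the lists an estimated correlation, fry and a rank-based camera. An offset for GC content and length, and camera on lists without members at 0 counts in every library of a group, were added after the data had been seen. All 6 libraries were used.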

Results

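Poly(A) RNA of 4T1 mouse mammary carcinoma cells grown in collagen I gels was sequenced in 3 control libraries, from cells that received Cas9 with control guides, and 3 libraries from cells that received Cas9 with guides named for FGFR2, called KO libraries here after their label. FGFR2 is a receptor tyrosine kinase for fibroblast growth factors (FGFs). The libraries held between 15531790 and 20447719 counts. The comparison asks how the transcriptome of these cells in a collagen matrix differs between the FGFR2 KO and the control guides. Replicates of a group differed little from each other, with a biological coefficient of variation of 4.00%, and every pair of replicates still differed by more than counting noise, with a chi-square per degree of freedom of 2.29 to 2.69 between control libraries, 3.85 to 4.87 between KO libraries and 43.8 to 51.1 between groups.

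Fgfr2 transcripts were present in all libraries, at 81.2 CPM (KO replicate 2) to 106 CPM (control replicate 3). The gene (chromosome 7, 130162451 to 133123350, minus strand) stood at 99.7 ± 5.82 CPM in the control libraries and 92.6 ± 10.4 CPM in the KO libraries (SD, n = 3 each), with 1777, 1948 and 1649 counts in control replicates 1 to 3 and 1896, 1589 and 1928 in KO replicates 1 to 3. The log2 fold change was -0.11 (SE 0.056, 95% interval -0.22 to 0.01, edgeR quasi-likelihood adjusted p = 0.113), so the interval leaves out a fall to a level below 0.859 of the control. A total over the gene does not test the label, because the labels give neither the exon that the guides cut nor whether the cells were a pool or a clone, and a frameshift need not lower the transcript. Without KO replicate 1 the log2 fold change was -0.17 with an edgeR adjusted p of 0.0081, and over all alternatives the adjusted p ran from 0.0081 to 1. Without KO replicate 2, the library with the lowest value, it was -0.017 (edgeR adjusted p = 0.809), so the estimate rests largely on that library. Of the 27 annotated transcript models of Fgfr2, 26 lie within 130162451 to 130266263, and 1 reaches to the gene's far end through exons shared with Ctbp2 (at 133081757 to 133081860 and 133123141 to 133123350).

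Fgfr1, a second receptor of the family (chromosome 8, 25513654 to 25575718), fell from 26.3 ± 0.774 CPM to 14.2 ± 1.97 CPM (SD, n = 3), a log2 fold change of -0.89 (SE 0.092, edgeR adjusted p = 2.03e-10). Fgfr3 was higher, at 7.81 ± 0.554 CPM in the control and 9.73 ± 1.28 CPM in the KO libraries (log2 fold change 0.31, SE 0.13, edgeR adjusted p = 0.0388). That call was lost with DESeq2 (adjusted p = 0.11), limma-voom (0.0535), upper quartile scaling (0.0563) and a minimum fold change of 1.5 (1), and without control replicate 2 (0.0956), control replicate 3 (0.119) or KO replicate 1 (0.231). Fgfr4 had 1 count over all libraries and was not tested. Among 13 tested FGF receptors and signalling partners, 3 rose and 4 fell (camera adjusted p = 0.646). Fgfbp1, a secreted carrier that frees FGFs from the matrix, fell by 1.63 on the log2 scale from 59.3 to 19.2 CPM, while of the heparan sulfate proteoglycans Sdc1 and Gpc1 rose by 0.35 and 0.32 and Sdc4 fell by 0.10. Of the 21 listed genes of the FGF family itself, 4 could be tested, each near or below 5 CPM. Fgf11 fell from 5.31 to 1.81 CPM and Fgf7 rose from 0.520 to 1.20 CPM, while Fgf1 and Fgf20 did not pass the test.

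The transcriptome as a whole differed widely, mostly by small amounts. Of 12158 tested genes, 6639 (54.6%) changed, 3300 up and 3339 down, with a median absolute log2 fold change of 0.34 among them. At least 2-fold differences were found for 350 genes that rose and 471 that fell, and at least 4-fold differences for 129 and 91. Tested against a minimum fold change of 1.5, 907 genes passed, 402 up and 505 down, and 65 of 157 genes named by the fixed rule lost their call. The 3 KO libraries lay entirely to one side of the 3 control libraries for 59.5% of tested genes, where chance gives 10%.

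The largest rise among genes with a mean of at least 5 CPM was that of Saa3, an acute phase serum amyloid gene, which went from 0.458 ± 0.288 to 24.9 ± 2.81 CPM (SD, n = 3), 51.2-fold. Wnt11, a Wnt ligand of the noncanonical branch, rose 46.5-fold to 21.7 ± 0.422 CPM. The matrix genes Postn (periostin) and Col12a1 rose 21.2-fold and 14.7-fold to 33.1 and 21.8 CPM. Krt14, a keratin of basal epithelial cells (chromosome 11, 100203162 to 100207548), was the most abundant of this group: it rose 15.9-fold from 60.2 ± 1.08 to 957 ± 18.0 CPM (edgeR adjusted p = 7.45e-42). The rest of the 10 were Kif26b (27.0-fold), the secreted protein Scube3 (26.8-fold), Odf3l1 (24.5-fold), the phosphatase gene Acpp (15.3-fold) and the semaphorin Sema3c (14.9-fold).

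The largest falls included genes usually studied in leukocytes. Itgb2, the integrin beta chain of leukocytes (chromosome 10, 77530252 to 77565708), fell by 4.06 on the log2 scale from 126 ± 7.55 to 7.50 ± 1.80 CPM (SD, n = 3), and the receptor gene Lilr4b fell by 4.58 from 19.3 to 0.804 CPM. Csf2, which encodes the cytokine GM-CSF (chromosome 11, 54247271 to 54249667), fell by 3.66 from 48.3 ± 1.02 to 3.81 ± 0.620 CPM. Txnip, an inhibitor of thioredoxin and of glucose uptake (chromosome 3, 96557957 to 96561883), fell by 2.90 from 438 ± 4.42 to 58.5 ± 0.860 CPM (edgeR adjusted p = 7.08e-37). The remaining falls were those of Unc13a (-4.13), Add2 (-3.43), the drug efflux transporter Abcb1a (-3.41), Calr4 (-2.99), Fer1l6 (-2.82) and the membrane transporter Slc4a11 (-2.76).

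Transcripts that report on ERK signalling, the main kinase cascade downstream of FGF receptors, were mostly lower. Of 22 genes in the list of ERK pathway feedback and target genes, 16 fell, 3 rose and 3 did not pass the test, with a median log2 fold change of -0.41. The list passed camera with an adjusted p of 1.75e-05, a call lost with an estimated correlation (camera adjusted p = 0.122). The ETS transcription factors Etv1, Etv4 and Etv5 fell by 0.85, 0.49 and 0.55, the Sprouty inhibitors Spry1 and Spry4 by 0.65 and 0.79, and the related Spred1, Spred2 and Spred3 by 0.33, 0.28 and 0.99. The phosphatases Dusp4 and Dusp5 fell by 0.59 and 0.50. Cyclin D1 (Ccnd1) fell by 0.55 from 1978 ± 28.6 to 1351 ± 35.9 CPM and Ier3 fell by 0.87 from 719 ± 7.48 to 393 ± 5.30 CPM (SD, n = 3). Phlda1 fell by 0.52, and Myc, Sh2b3 and Elk3 fell by 0.16, 0.21 and 0.23. Dusp6 and Spry2, both direct feedback inhibitors, did not pass the test, at -0.04 (SE 0.038, edgeR adjusted p = 0.396) and 0.04 (SE 0.051, edgeR adjusted p = 0.532), and neither did Il17rd at 0.20. Epha4 rose by 1.48 and Fosl1, a subunit of AP-1, by 0.30, and Epha2 rose by 0.10, a call lost with upper quartile scaling (edgeR adjusted p = 0.0513) and without control replicate 3 (0.0567).

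**Figure D1:**
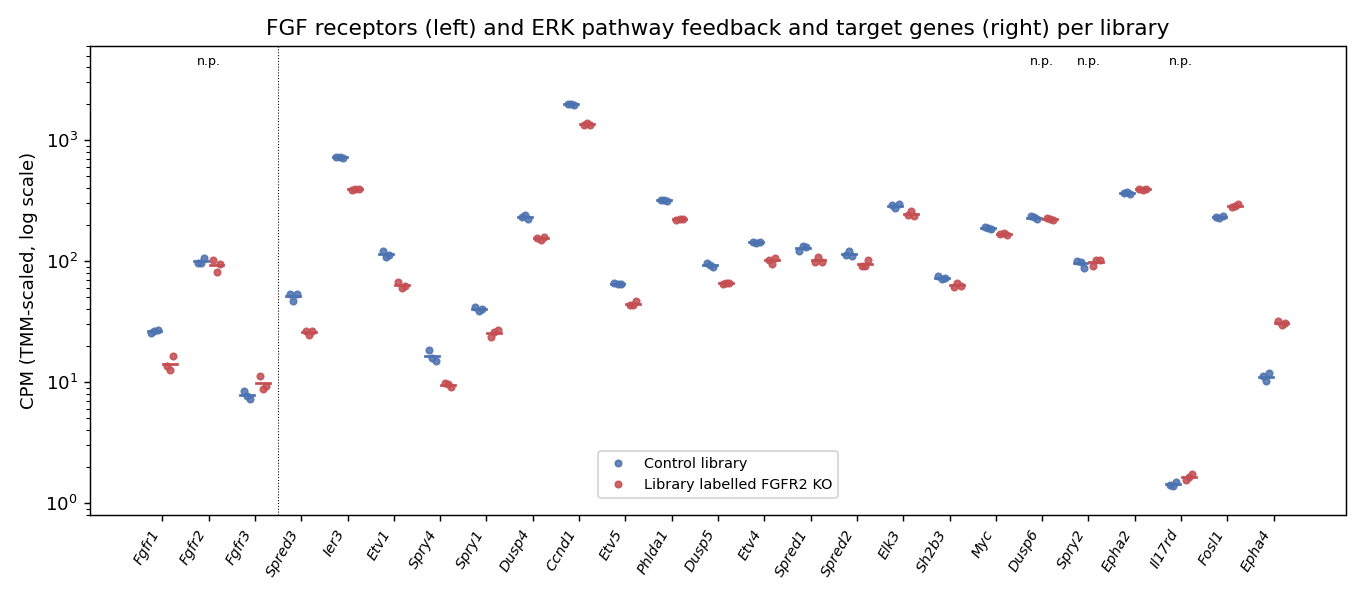
CPM after TMM scaling (vertical, log scale) of the 3 tested FGF receptors, left of the dotted line, and of the 22 ERK pathway feedback and target genes, ordered by log2 fold change, with 1 point per library (control blue, KO red), bars at group means and n.p. on genes that did not pass the test. Fgfr2 overlaps between the groups at about 99.7 and 92.6 CPM, whereas the 3 KO libraries lie below the 3 control libraries for Fgfr1 and for the 16 genes that fell.

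The immediate early genes, which respond within minutes to growth factors and to tissue dissociation, moved in both directions. Of 19 tested, 11 rose and 8 fell (camera adjusted p = 0.201). Egr1 fell by 1.31 from 554 ± 16.5 to 223 ± 14.5 CPM (SD, n = 3), Egr3 from 68.6 to 28.7 CPM and Zfp36 by 0.59 on the log2 scale, whereas Atf3 rose by 0.84. EGF family ligands also split, with 4 of 8 up and 2 down (camera adjusted p = 0.646). Areg rose by 0.61 while Tgfa and Hbegf fell by 0.45 and 0.41. Among 19 other receptor tyrosine kinases 6 rose, including Met (0.41) and the collagen receptor Ddr1 (0.36), and 7 fell, including Ephb2 (-0.57) and Ephb4 (-0.36), with no common direction (camera adjusted p = 0.955).

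Genes of glycolysis and of the response to low oxygen formed the list that stood out most. All 29 tested members changed, 26 down and 3 up, with a median log2 fold change of -0.85 (camera adjusted p = 1.44e-47, and 0.0046 with an estimated correlation). The falls covered glucose uptake (Slc2a1, -0.94) and glycolytic enzymes from Hk2 (-0.85) to Ldha (-0.68). Aldoa fell by 1.23 from 1732 ± 14.5 to 738 ± 9.80 CPM, Pgk1 by 1.18 from 1267 ± 19.1 to 559 ± 8.10 CPM and Aldoc from 72.4 ± 1.67 to 11.2 ± 0.168 CPM (SD, n = 3). Among genes induced by low oxygen, the carbonic anhydrase Car9 fell by 2.32 from 134 ± 2.56 to 26.8 ± 2.07 CPM, Bnip3 by 1.88 and Pdk1 by 1.73. The 3 exceptions were Pfkfb3 (1.28), Ankrd37 (0.67) and Adm (0.52), which rose.

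Lipid synthesis genes were lower as well. Of 24 tested genes of cholesterol synthesis and uptake, 22 fell and 0 rose (median -0.47, camera adjusted p = 8.03e-11, and 0.017 with an estimated correlation). Insig1, a sterol-regulated membrane protein, fell by 1.34 from 449 ± 13.2 to 178 ± 2.18 CPM (SD, n = 3), lanosterol synthase (Lss) by 0.78, Fdft1 by 0.53 and Msmo1 by 0.50. Of 15 fatty acid synthesis genes 12 fell and 2 rose (median -0.40, camera adjusted p = 3.46e-08, and 0.020 with an estimated correlation). The desaturase Scd2 fell by 1.26 from 1540 ± 20.1 to 642 ± 12.6 CPM, Scd1 from 130 to 45.8 CPM, and Fads1 and Fads2 by 0.91 and 0.86 on the log2 scale, while fatty acid synthase (Fasn) fell by 0.14.

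Most cytokine and chemokine genes fell. Of 27 tested, 22 fell and 4 rose (median -0.96, camera adjusted p = 2.05e-12, and 0.017 with an estimated correlation). Besides Csf2, Csf3 (G-CSF) fell by 1.60 from 247 ± 6.08 to 81.3 ± 1.11 CPM (SD, n = 3), the neutrophil attractant Cxcl1 by 1.30 from 568 to 231 CPM and Il1a by 1.46. Csf1, Tslp, Il6 and Cxcl15 rose, the last 2 from very low levels, with Il6 at 0.133 CPM in the control and 3.60 CPM in the KO libraries. NF-kB feedback genes had 9 of 19 members down and 3 up (median -0.13, camera adjusted p = 0.0096). This call was lost with an estimated correlation (camera adjusted p = 0.11) and with the rank-based test (adjusted p = 0.0897). Nfkbia, the inhibitor of NF-kB, fell by 0.89, Nfkbiz by 0.92, Tnfaip2 by 0.84 and the adhesion molecule Vcam1 by 1.02. The type I interferon response had 10 of 23 members down, including Oasl1 (-1.15) and Irf9 (-0.62), and 5 up, including Ifit2 (0.64), and did not pass (camera adjusted p = 0.289). Of 16 genes of MHC class I presentation 9 fell, such as the peptide transporter Tap2 (-0.79) and Irf1 (-0.52), and 3 rose (camera adjusted p = 0.0714).

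Of 15 tested basal keratin and myoepithelial genes, 9 rose and 3 fell (median 0.62, camera adjusted p = 1.48e-11, and 0.020 with an estimated correlation). Next to Krt14, Krt16 rose by 2.75 from 9.45 ± 0.772 to 63.5 ± 1.74 CPM (SD, n = 3), Sfn by 1.02 and the desmosomal gene Perp by 0.62. Krt15 and the laminin chain Lama3 fell by 0.63 and 0.37. Of 8 luminal and milk genes, 3 fell and 1 rose (median -0.27, camera adjusted p = 6.58e-05, and 0.046 with an estimated correlation). This call was lost with limma-voom (adjusted p = 0.0508) and the rank-based test (0.219). The 3 that fell were secreted proteins: Lcn2 (lipocalin) fell by 2.28, osteopontin (Spp1) by 1.31 from 1038 ± 9.15 to 418 ± 13.4 CPM, and the casein Csn3 by 5.30 from 4.28 to 0.101 CPM. The luminal transcription factor Gata3 rose by 0.49. The 28 epithelial junction and identity genes showed no common direction, with 8 up and 9 down (camera adjusted p = 0.955). Krt18 and Krt19 fell by 0.61 and 0.56, whereas the transcription factor Grhl1 rose from 0.474 to 8.02 CPM, Ovol1 by 1.72 on the log2 scale and E-cadherin (Cdh1) by 0.25.

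Mesenchymal and EMT genes (those raised when epithelial cells take on mesenchymal features) had 8 of 14 members up and 3 down (median 0.39, camera adjusted p = 4.16e-05, and 0.043 with an estimated correlation). Besides Postn, Sparc rose by 1.01 from 115 ± 6.44 to 231 ± 9.25 CPM (SD, n = 3), while vimentin (Vim) fell by 0.31 from 2433 to 1963 CPM, and the EMT transcription factors Zeb2 and Twist1 fell by 0.40 and 0.29. The rank-based test did not call this list (adjusted p = 0.128). Acta2 had 0 counts in the control libraries and 51 in the KO libraries, which is at least 3.98 on the log2 scale over a floor of 3 counts for the group. The list's median was 0.39 with this member at its bound, and without Acta2 the list had a median of 0.33 and a camera adjusted p of 7.03e-05.

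TGF beta family targets had 12 of 20 members up and 6 down (median 0.28, camera adjusted p = 1.59e-08, and 0.020 with an estimated correlation). The inhibitors of differentiation Id1, Id2 and Id3, which respond to BMPs as well as to TGF beta, rose by 2.75, 1.37 and 1.36. Id1 went from 26.9 ± 0.592 to 181 ± 9.87 CPM (SD, n = 3), and Ltbp2, a matrix protein related to the TGF beta binding proteins, rose by 1.29. Members that fell included Tgfb1 (-0.26), Inhba (-0.55) and Serpine2 (-0.71). YAP and TEAD targets had 11 of 20 up and 6 down (median 0.32, camera adjusted p = 1.51e-04), with Cyr61 (1.14), Ctgf (1.06), Crim1 (1.12) and Gadd45b (1.19) among the risers and Ankrd1 (-0.27) and Axl (-0.23) among those that fell. With an estimated correlation the YAP and TEAD call was lost (camera adjusted p = 0.150), and the rank-based test called neither list (adjusted p = 0.0897 for TGF beta and 0.148 for YAP and TEAD).

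Actomyosin and motility genes had 13 of 28 up and 4 down, with a small median of 0.06 (camera adjusted p = 0.0489, and 0.162 with an estimated correlation). Rnd3 rose by 1.21, Tpm1 by 0.57 and the actin bundler Fscn1 by 0.49, and cortactin (Cttn) fell by 0.50. The list's call was also lost with upper quartile scaling (camera adjusted p = 0.0616), the filter of 5 CPM (0.0808) and the replicate number as a block (0.0509). It was lost as well without control replicate 1 (0.0705) and without KO replicate 2 (0.0511). Of 13 Wnt targets and ligands 5 rose and 4 fell (camera adjusted p = 0.401), with Lgr4 up by 1.64, Notum up by 0.62, Wnt10b down (-1.09) and Wnt7b down (-0.47). Of 12 Notch pathway genes 7 rose and 3 fell (camera adjusted p = 0.252). Hey1 rose by 3.10 from 0.408 to 3.69 CPM and Jag1 by 0.38, whereas Dll4 and Nrarp fell by 0.83 and 0.79.

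Matrix genes changed strongly in both directions. Of 20 collagens and other matrix genes 7 rose and 9 fell (camera adjusted p = 0.289). The collagen VI chains Col6a1 and Col6a2 rose from 101 to 281 and from 12.0 to 68.1 CPM, and thrombospondin (Thbs1) by 1.22 from 516 ± 12.9 to 1199 ± 71.2 CPM (SD, n = 3), whereas Col8a1 fell by 1.45 from 467 ± 7.30 to 171 ± 2.39 CPM. Of 22 matrix proteases and inhibitors 9 rose and 11 fell (camera adjusted p = 0.0526). The secreted metalloproteinases Mmp3, Mmp9 and Mmp13 fell by 1.48, 1.42 and 2.28, Mmp9 from 365 ± 4.69 to 137 ± 4.83 CPM. The membrane-anchored Mmp14 and the inhibitor Timp2 rose by 0.78 and 0.86. Integrins had 4 of 13 up and 4 down (camera adjusted p = 0.955): next to the fall of Itgb2, the beta chains Itgb3, Itgb5 and Itgb6 rose by 1.81, 1.04 and 2.21.

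Of 29 S phase genes 25 rose and 0 fell (median 0.24, camera adjusted p = 1.66e-05). The list's call was lost with an estimated correlation (camera adjusted p = 0.0586). Mcm5 rose by 0.44, Rrm2 by 0.49, Tyms by 0.57 and Pcna by 0.33 from 297 ± 4.79 to 374 ± 5.68 CPM (SD, n = 3). Of 30 G2 and M phase genes 17 rose and 0 fell, with a median of 0.11 that did not pass (camera adjusted p = 0.0771), and Mki67 rose by 0.24 and Nuf2 by 0.45. Of 17 p53 targets 8 rose and 3 fell (camera adjusted p = 0.0501), with Fas at 1.20 and Plk2 at 0.66 against Trp53inp1 at -0.89. Among the 11 tested histone genes 3 fell and 0 rose (camera adjusted p = 0.940), and these are poorly captured in poly(A) libraries.

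Of 25 genes of the unfolded protein and integrated stress responses 15 rose and 3 fell (median 0.20, camera adjusted p = 0.016, and 0.138 with an estimated correlation, which ends the call). Calreticulin (Calr) rose by 0.70, Phgdh by 0.50 and Slc3a2 by 0.43, and Xbp1 fell by 0.44. NRF2 and oxidative stress genes had 10 of 20 up and 7 down (camera adjusted p = 0.201), with Nqo1 up by 1.37, Gsta4 by 0.65 and Txnrd1 by 0.44, and Gsr down (-0.58). Of 11 tested mitochondrially encoded genes 7 rose and 0 fell (median 0.57, camera adjusted p = 2.44e-06, and 0.138 with an estimated correlation, which ends the call), for example mt-Nd5 by 0.77 and mt-Cytb by 0.63. All genes with a symbol starting in mt-, in the list or not, took 0.988% ± 0.0335 of the counts in the control and 1.41% ± 0.0251 in the KO libraries (SD, n = 3). Genes with symbols of Rpl or Rps and a digit, mostly ribosomal protein genes, took 5.74% ± 0.120 of the counts in the control and 5.22% ± 0.0639 in the KO libraries. Of the mitochondrial genes, mt-Co2, mt-Co3 and mt-Atp6 stood at about 1 CPM beside 3483 CPM for mt-Co1, so the table does not hold most of their reads.

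Most markers of other cell types were too low to be tested. Of 16 immune cell markers 3 could be tested, of 12 endothelial markers 2, and of 14 fibroblast markers 4. The pan-leukocyte gene Ptprc had 1 count in the control and 2 in the KO libraries, and Adgre1, Tyrobp and S100a9 had 0. Cd68 fell from 13.7 to 5.97 CPM, and Cd74 and Csf1r did not pass the test. Gsn fell by 0.18 and Eng rose by 0.56, Pdgfra (36.4 CPM in the control and 39.4 CPM in the KO libraries) and Fbln1 did not pass the test, Plvap fell from 42 to 4 counts, and Mfap5 rose from 1 to 65 counts.

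**Figure D2:**
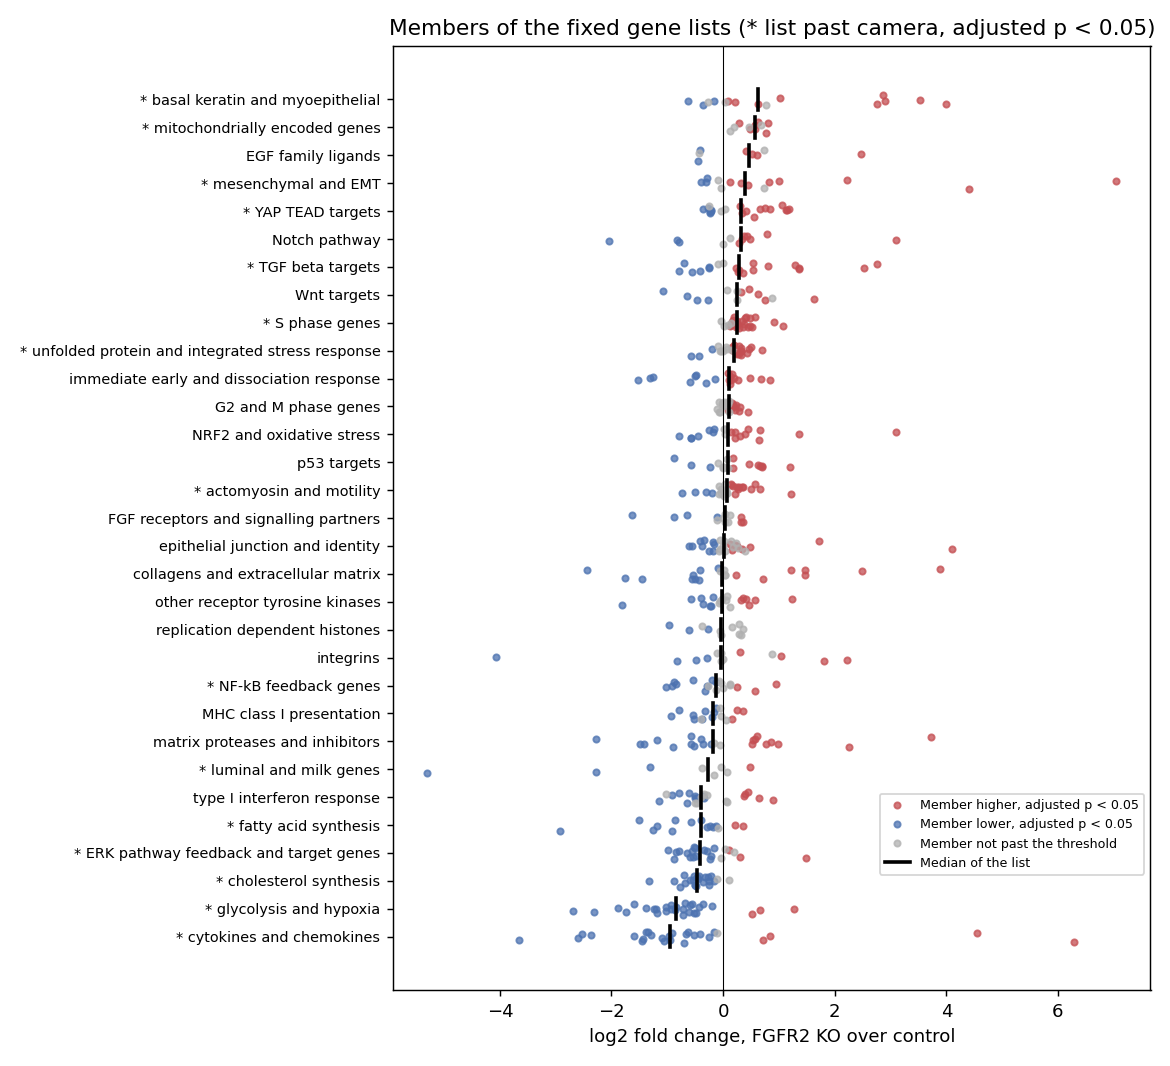
Log2 fold changes of KO over control for the tested members of the 31 lists with at least 5 tested members, red where higher, blue where lower and grey where not past the threshold, with black bars at list medians and asterisks on the 15 lists past camera. Glycolysis and hypoxia genes lie mostly left of 0 (median -0.85) and basal keratin genes reach far to the right (median 0.62), and the point of Acta2 is a fitted value over control libraries at 0.

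In all, 15 of 31 lists passed camera, 8 up and 7 down, and with an estimated correlation 8 passed. Adjusted over the list alone, the counts of changed members were as given in 30 of the 35 lists. They were 13 up and 6 down for actomyosin, 12 up and 7 down for TGF beta targets, 8 up and 4 down for p53 targets, 0 up and 23 down for cholesterol synthesis, and 0 up and 1 down for histones. Among the 31 lists tested, median and mean differed in sign in 5, none of which passed camera: FGF receptors and partners (median 0.03, mean -0.16, tested as down), immediate early genes (0.11 and -0.15, down), collagens (-0.02 and 0.17, up), matrix proteases (-0.19 and 0.03, down) and integrins (-0.03 and 0.03, up).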

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

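The GC content and length offset and the lists without members at 0 counts in a group were chosen after the data had been seen, and the other alternatives before. The number of changed genes stayed within 1.5 times of 6639 under every alternative but 1: it was 5753 with DESeq2, 6616 with limma-voom, between 6572 and 6652 with other scalings, 6694 without a low count filter, 5901 with the stricter one, 6808 with the GC and length offset, and between 5922 and 6276 with 1 library left out. A minimum fold change of 1.5 left 907, since the test then asks for more than a difference from 0. Scaling moved the median of all genes by less than 0.03 on the log2 scale. For the lists, 15 passed in the main test and 8 with an estimated correlation, and the cause of the lost calls was not tested. Among the lost calls, the estimate lay below the preset 0.01 for NF-kB feedback (-0.039) and actomyosin genes (0.0065). That argues against a higher correlation as the cause for those lists. The estimate lay above 0.01 for mitochondrially encoded (0.30), YAP and TEAD (0.11), ERK (0.093), S phase (0.027) and stress response genes (0.011). Fry, which asks only whether a list's own genes move one way, called 27, and the other alternatives between 11 and 19. The log2 fold change of Fgfr2 ran from -0.17 (without KO replicate 1) to -0.017 (without KO replicate 2) with 1 library left out. Only the first of these passed the threshold, and the cause was not tested.

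The replicate number as a block gave 6443 changed genes, 6428 of them shared, 14 lists (without actomyosin, at a camera adjusted p of 0.0509) and -0.11 for Fgfr2. Same-numbered libraries did not deviate together (correlations of -0.03, -0.003 and -0.06 across genes) and 0 of 6 libraries correlated best with their own number, so the numbers were not read as pairs.

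Of 157 named genes, 65 lost their call with the minimum fold change of 1.5, and 4 under another alternative: Fgfr3, Epha2, Hist1h1e and Hist1h2bg. Spry2, not past the threshold, ran from -0.014 to 0.089 with 1 library left out. The direction of the test turned only in lists not past the threshold, with these medians. Collagens stood at -0.021 with limma-voom and -0.022 in the rank-based test. Epithelial genes stood at 0.00048 with the stricter filter, 0.038 with DESeq2, 0.023 with fry and in the rank-based test, 0.022 with limma-voom and 0.00047 with upper quartile scaling. Immediate early genes stood at 0.11 in the rank-based test. Other receptor tyrosine kinases stood at -0.016 with the GC and length offset and -0.033 without a filter, and ran from -0.047 to 0.0030 with 1 library left out. Integrins ran from -0.075 to -0.025, and histones from -0.24 to 0.20, in the same way. Histones stood at 0.16 with DESeq2 and 0.29 without a filter. The cause was not tested for any of these. In 29 cases a list passed only under an alternative, among them p53 targets and matrix proteases. The planned pseudocounts were not run because the table holds counts.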

Other observations

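The gene families by symbol, the lists of oxygen, BMP and MondoA response genes, the GC and length offset, the lists without members at 0 counts in a group, and the genes of the first paragraph were chosen after the results were seen, as were the tests of repeated sequencing, of depth, of an exchanged library, of edits and of cultures. Several genes outside the lists, not among the 10 largest rises or falls, also changed. Aldh3a1, an aldehyde dehydrogenase, rose from 81.3 ± 3.75 to 398 ± 4.68 CPM (SD, n = 3), Ass1, an enzyme of arginine synthesis, from 11.4 ± 1.20 to 90.3 ± 4.05 CPM, and the proteases Prss23 and Masp1 from 7.65 to 89.5 and from 6.62 to 59.5 CPM. Sulf2, an enzyme that removes sulfate groups from heparan sulfate, the coreceptor of FGFs, rose from 6.14 to 39.0 CPM. Bhlhe41, a transcriptional repressor, fell from 153 ± 7.76 to 35.5 ± 1.05 CPM, the protease Prss22 from 149 to 32.9 CPM and the TNF receptor family member Tnfrsf9 from 29.7 to 5.30 CPM.

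Among 126 families of genes that share a symbol stem, only keratins passed camera (6 of 13 up and 6 down, adjusted p = 0.0039, and 0.987 with an estimated correlation). With an estimated correlation no family had a camera adjusted p below 0.987. Not past camera were proteasome subunits (Psmd, 13 of 14 up and 1 down) and mitochondrial ribosomal proteins (Mrpl, 23 of 48 up and 2 down, and Mrps, 12 of 29 up and 0 down). The stems of cytosolic ribosomal proteins did not pass either (Rpl, 29 of 46 down and 4 up, and Rps, 30 of 42 down and 5 up). A stem takes in every symbol with those letters before its first digit, so these counts can include genes that are not ribosomal proteins. Semaphorins had 9 of 15 members down and 2 up, against the rise of Sema3c.

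The first pattern is the number of changed genes, 6639. The 10 splits of 6 libraries are too few for a share under 0.05: 1 split, the real one, gave 6639 genes, and the highest of the others 0. For the lists 1 split, again the real one, gave 15 past camera, and the others gave between 5 and 8. Each of the other splits mixed control and KO libraries on both sides, so it kept part of the group difference. Its list calls therefore do not show how often camera calls lists without a difference. Mixing also widened the spread within each side, so the 0 changed genes there say little about the 6639. Repeated sequencing of 1 library per group is argued against by the smallest chi-square of a replicate pair, 2.29 per degree of freedom. A GC or length trend is argued against by the 6808 genes called with an offset for it. Windows of neighbouring genes beyond every shuffled order, where the largest median was 0.36 in size, held 0% of changed genes, and window medians ran from -0.23 to 0.15. That argues against a gained or lost chromosome segment that shifts a whole window by more than 0.36. A smaller shift or a segment shorter than a window could not be seen in this way. A difference between the cells of the groups that is not due to FGFR2, such as clonal drift or cultures handled apart, stays open, because the labels name neither clones nor cultures.

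The second pattern is Fgfr2 itself, whose total did not pass the threshold in libraries labelled FGFR2 KO. Too few counts to see a fall to 50% is argued against by the lower bound of the interval, -0.22, and an exchange of a library between groups by distances between groups that were at least 2.17 times the largest within a group. Edits that disrupt the protein and leave the transcript at 0.930 of its control level may account for the pattern. Gene totals hold no base calls, so this cannot be told apart from cells in which the gene was left intact. The falls of Etv1, Etv4, Etv5, Spry1 and Spry4 may reflect a lower FGF receptor output, which was not tested. Of the 22 ERK pathway genes 16 fell, but Dusp6, Spry2 and Il17rd did not pass the test and Epha4, Fosl1 and Epha2 rose. The list's call was lost with an estimated correlation (camera adjusted p = 0.122), and Fgfr1 fell too. These falls settle neither whether an FGF receptor is involved nor which one.

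The third pattern is the fall of glycolysis and hypoxia genes. A GC or length trend is argued against by their median of -0.84 with the offset. A lower glycolytic demand without a weaker oxygen response is argued against by 19 oxygen response genes outside the list, of which 13 fell and 0 rose. Their median was -0.47 (camera p = 6.16e-06, and an adjusted p of 0.016 with an estimated correlation). The 19 include the sugar phosphate and glycogen enzymes Pgm2 (-1.42), Gbe1 (-0.84), Gys1 (-0.73) and Pgm1 (0.09), which do not separate these explanations. Falls outside that metabolism included Mxi1 (-0.62), Higd1a (-0.47) and Egln1 (-0.45). Part of the oxygen response may have been weaker in the KO cells, but not all of it: Kdm3a, Hilpda, Vhl, Insig2, Narf and Pgm1 of these 19 did not pass the test, and Pfkfb3 (1.28), Ankrd37 (0.67) and Adm (0.52) of the list itself rose. Whether that follows from the genotype or from gels that differed in cell density or oxygen cannot be told apart: the mean difference of the list between groups, -0.84, is fully shared with the grouping, and the labels give neither cell number nor time in culture.

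Id1, Id2 and Id3 lead to the hypothesis of a wider BMP response in the KO cells. Of 11 BMP response genes outside the TGF beta list, 63.6% rose, including Atoh8 (4.05) and Smad9 (2.98), both from about 0.5 CPM, and Dlx1 (1.26). Camera gave p = 0.0058 for this set, and 0.0929 with an estimated correlation. Id4 fell by 0.54 and Hes1 stood at 0.00. These values are consistent with the hypothesis but rest largely on genes of low expression.

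Txnip, the most abundant of the large falls, is induced by the glucose sensor MondoA, as is Arrdc4. Arrdc4 fell by 2.61, from 12.8 to 2.09 CPM, which is consistent with lower MondoA activity as a candidate explanation, although only 2 target genes bear on it. Txnip fell in the same libraries as the glycolytic genes, and the data hold no measurement of glucose.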
